A study of Drosophila melanogaster with 3 samples.

How the data were processed

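Chromatin immunoprecipitation with sequencing (ChIP-seq) was performed on Drosophila melanogaster larvae of a line that stably carried Lola-RI, an isoform of the BTB zinc finger protein encoded by lola, with enhanced green fluorescent protein (eGFP) at its C terminus. Per the labels, the material was whole larvae of the third instar, at the wandering stage, with both sexes pooled, the antibody was directed against GFP, and chromatin was sheared by sonication to fragments of 200 to 800 bp. The antibody field of the labels names lola, while their description states an anti-GFP immunoprecipitation. There were 3 biological replicates in 1 group, numbered as in the labels, and no comparison group. The control library named in the labels was not analysed here.

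Peaks were called by the authors in each replicate separately and once on the 3 replicates pooled, each against the same control file, and a further list held peaks of the pooled list that passed an irreproducible discovery rate (IDR) threshold, per the deposited text descriptions. The aligner, the peak caller, their versions and the value of the IDR threshold are not given in the sources used here. Coordinates are on dm6, per the labels and the file headers, and are given 1-based. The score of each peak is the authors' own value in the deposited lists, its scale is not given in the sources used here, and it was used only to rank peaks within a list. The −log10 q value that the authors gave each peak in the deposited lists reached a ceiling shared by all 9202 IDR peaks, so it was not used for ranking. Each replicate list and the pooled list held 30000 peaks, a common length that does not follow the strength of a library, and the IDR list was the same set as the 9202 highest-scoring peaks of the pooled list. The deposited peak lists hold no read counts, so the sequencing depth is unknown, and intervals cover counting error over peaks or genes only. Peaks and genes are not replicates. For the main results, values are therefore also given singly or as mean ± SD over the 3 replicate lists, each shortened to its 9202 highest-scoring peaks. They are not given for every gene list and motif. The IDR list was made from the same 3 replicates and is not independent of them.

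Peak positions were annotated with Ensembl release 115 gene models on the release 6 genome, with transposable elements left out, for chromosome arms X, 2L, 2R, 3L, 3R and chromosome 4. Each summit took the first class that applied of promoter (within 500 bp of an annotated transcription start site, TSS), 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic. Shares per class were compared with 10000 random placements of the summits within their own chromosome, by a two-sided permutation test. Overlap of replicate lists by at least 1 bp was compared with 1000 random placements by a one-sided permutation test. X was compared with the autosome arms by an exact binomial test, two-sided. Summits in lola extended by 5000 bp on either side were compared with 10000 random windows of the same length, one-sided for more summits.

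A gene was called bound when an IDR summit lay within 500 bp of any of its TSSs. A summit near the TSSs of several genes counted for each of them, so p values for lists of clustered genes may be too small. Bound shares of 34 gene lists were compared with all 13945 protein-coding genes, or with all 18164 genes for the tRNA and the small nucleolar and small nuclear RNA lists, by Fisher's exact test, two-sided. The lists covered axon guidance, BTB domain transcription factors, ecdysone response, ecdysteroid synthesis, the Notch, Wnt, Hedgehog and Dpp, EGFR, JAK-STAT and Hippo pathways, Hox genes, imaginal patterning transcription factors, circadian clock, cell death, cytosolic ribosomal proteins, translation initiation factors, proteasome, oxidative phosphorylation, heat shock proteins, salivary gland glue and 71E genes, cuticle proteins, fat body, muscle, neurons, glia, neural progenitors, haemocytes, midgut digestion, germline, antimicrobial peptides, chemosensory receptors, histone genes, tRNA genes, and small nucleolar and small nuclear RNA genes. Of the listed symbols, 4 had no match in the annotation and 13 were matched through a synonym, a step set after the data were seen. Consensus motifs, 19 in number, and all 2080 6-mers with their reverse complements were counted in 101 bp windows centred on summits and in windows of that width 500 bp to either side, and compared by Fisher's exact test, two-sided. Adjusted p values are Benjamini-Hochberg values over the 7 classes, the 34 lists, the 19 motifs or the 2080 6-mers, and the threshold was 0.05.

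The design, gene lists, motifs, tests and the alternatives listed below, other than the 4 named last, were fixed before the data were examined. So was the rule for the genes named. It takes lola, the gene with the TSS nearest to each of the 15 highest-scoring IDR peaks, and up to 3 genes per list with the highest-scoring promoter summit. Other genes named were chosen after their values were seen, which is said where they occur. Alternatives covered the overlap rule, list length, promoter width, TSS set, summits anywhere in the gene, the midpoint of the region in place of the summit, the stronger 4601 IDR peaks, random gene lists matched on TSS number and gene length in 10 classes each, motif window and background, and leaving out each replicate in turn. Where a replicate was left out for location, peak density, gene lists or motifs, the shortened lists of the remaining replicates replaced the IDR list. For gene lists, a gene then had to be bound in each remaining list, a stricter rule. A call lost in this way does not show that the replicate left out carried it. Another 4 alternatives were added after the data were seen. They were 1 summit per merged region for location, the same for peak density, random placement on unmasked bases, and score correlation in the stronger 4601 peaks.

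The procedures for location, list agreement, gene lists and motifs were tested on simulated data. For the location of peaks, a promoter share of 48.6% was recovered among 9202 simulated summits made with 48.2%, and 0 of 7 classes passed the threshold for random summits. For the agreement of lists, 64.0% overlap was recovered from lists made with 63.6%. For the gene lists, 100% of 100 lists made with a raised share and 0.517% of 580 unchanged lists passed. The raised lists held 39 to 179 genes. The 100% therefore does not describe short lists such as Hox (8 genes) or circadian clock (10 genes). In that simulation genes were bound independently of each other, TSS number and gene length. It therefore does not give the rate of false calls in the real lists, where these matter. For the motifs, the planted word ranked 1 of 2080. Calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and numba 0.67.0, and figures were drawn with matplotlib 3.10.9.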

Results

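Binding of the tagged transcription factor Lola-RI was mapped by anti-GFP ChIP-seq in whole larvae of the third instar, at the wandering stage in which they leave the food before pupariation, in 3 biological replicates of 1 group. The design held no second condition. The comparisons it allows are between the replicates, between peaks and random positions of the genome, between lists of genes, and between sequence at summits and sequence beside them. The authors' IDR list held 9202 peaks in 7794 separate regions, which covered 4.10 Mb or 3.07% of the 6 chromosomes analysed. The replicate lists of 30000 peaks covered 8.55%, 8.58% and 8.89% of them. No peak lay on the Y chromosome or on unplaced sequence.

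The first question was where binding was strongest and whether the replicates found the same sites. The highest-scoring peak in all 3 replicates lay at Eip75B, an ecdysone-induced nuclear receptor gene, on 3L from 18024457 to 18030772 in dm6, with its summit 145 bp upstream of an internal TSS. The next peak lay at the promoter of Adk3, on 2R from 7244925 to 7247442, 38 bp upstream of the TSS. At rank 3 was a peak in a coding exon of Pabp2, a nuclear poly(A)-binding protein gene, on 2R from 8131028 to 8133204, 639 bp downstream of the TSS. At rank 4, on 3L from 18799900 to 18802041, was a peak at a promoter of ftz-f1, another nuclear receptor gene of the ecdysone cascade, with the TSS of the noncoding RNA gene lncRNA:CR45939 223 bp from the summit. The remaining 11 of the 15 highest-scoring peaks had their nearest TSS at mthl10, CG6426, Gapdh2, SLC5A11, Got1, IntS6, mlt, CG17746, CR33294, CG33523 and CG7920. Gapdh2 encodes a glycolytic enzyme and Got1 an aspartate aminotransferase. The summit assigned to Got1 was 2674 bp from its TSS, inside an intron of spin, and that assigned to mlt was 1173 bp from its TSS, inside an intron of KCNQ. The 15 peaks ranked between 1 and 36 in each replicate.

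**Figure D1:**
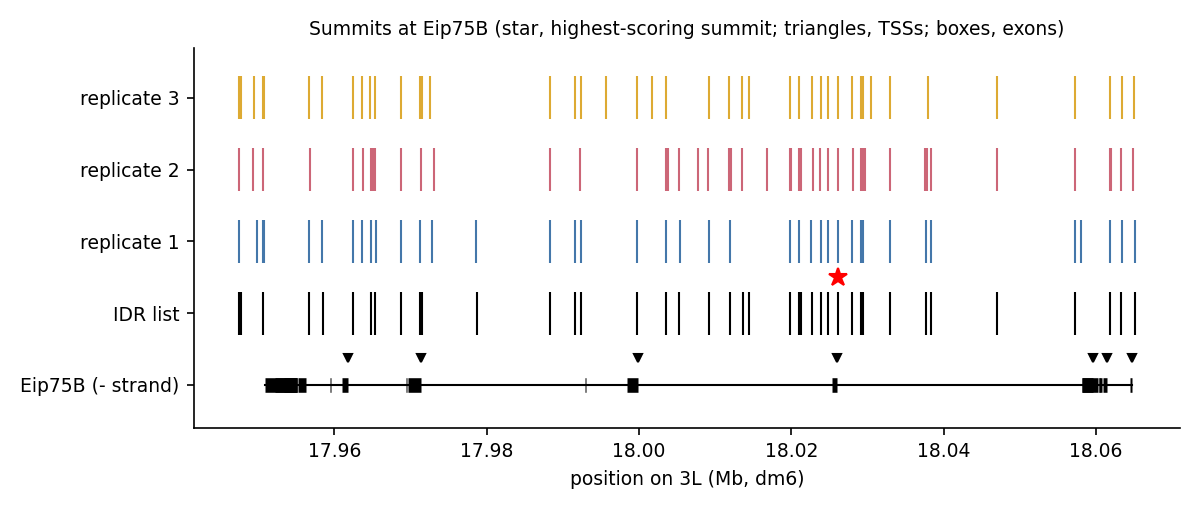
Positions of summits at Eip75B on 3L (dm6, Mb) in the IDR list and in the 9202 highest-scoring peaks of each replicate, above the exons (boxes) and TSSs (triangles) of the gene. The star marks the highest-scoring summit of the IDR list, at 18026177, which ranked 1 in all 3 replicates.

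Among the 9202 highest-scoring peaks of each replicate, 84.5% were shared between replicates 1 and 2, 82.7% between 1 and 3 and 83.6% between 2 and 3 (mean 83.6% ± 0.93 SD over the 3 pairs). Random placement gave 5.69%, and the permutation p was 0.001, the smallest that 1000 placements can give. Placement was uniform along each chromosome. The p therefore does not separate agreement on single sites from a preference for promoters common to the lists. Of the IDR peaks, 91.5%, 88.0% and 88.5% overlapped such a peak of replicates 1, 2 and 3 (mean 89.3% ± 1.88 SD, n = 3), and 6875 (74.7%) did so in all 3. In the full lists of 30000 the mean was 98.6% ± 0.711 (SD, n = 3). Of the fifth of IDR peaks with the highest scores, 99.9% were found in all 3 shortened lists, against 24.7% of the fifth with the lowest scores. Both the IDR list and the shortened lists end at 9202 peaks. Weak IDR peaks therefore lie near the cut and can fall past it in a replicate. In the full lists, 96.2% of all IDR peaks were found in all 3 replicates. Scores of shared peaks correlated across peaks with a Spearman coefficient of 0.825 for replicates 1 and 2, 0.763 for 1 and 3 and 0.762 for 2 and 3. Peaks are not independent replicates, and these coefficients describe the lists only.

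The next question was where the factor lay relative to genes. Promoters held 5109 of the 9202 summits, 55.5% (Wilson 95% interval 54.5 to 56.5), which was 4.09 times the 13.6% of random positions. The replicates gave 53.6%, 56.5% and 59.0% (mean 56.4% ± 2.70 SD). Coding exons held only 50 summits, 0.543% against 13.7% at random. Summits were also fewer than random in 3′ UTRs (1.25% against 4.41%), introns (28.5% against 39.4%) and intergenic sequence (12.7% against 27.4%). For each of these 5 classes the permutation p was 0.0002, the smallest that 10000 placements can give, with an adjusted p of 0.00028, and all 3 replicates lay on the same side of random. Annotated 5′ UTR sequence (0.75% against 0.778%, adjusted permutation p = 0.824) and other exons (0.717% against 0.814%, adjusted permutation p = 0.386) did not differ from random placement. With promoters taken from 1000 bp upstream to 100 bp downstream, the 5′ UTR share was 2.06% and lay above random (1.52%, adjusted permutation p = 0.000233). With promoters within 1000 bp on both sides it was 0.261% and lay below random (0.446%, adjusted permutation p = 0.00677).

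**Figure D2:**
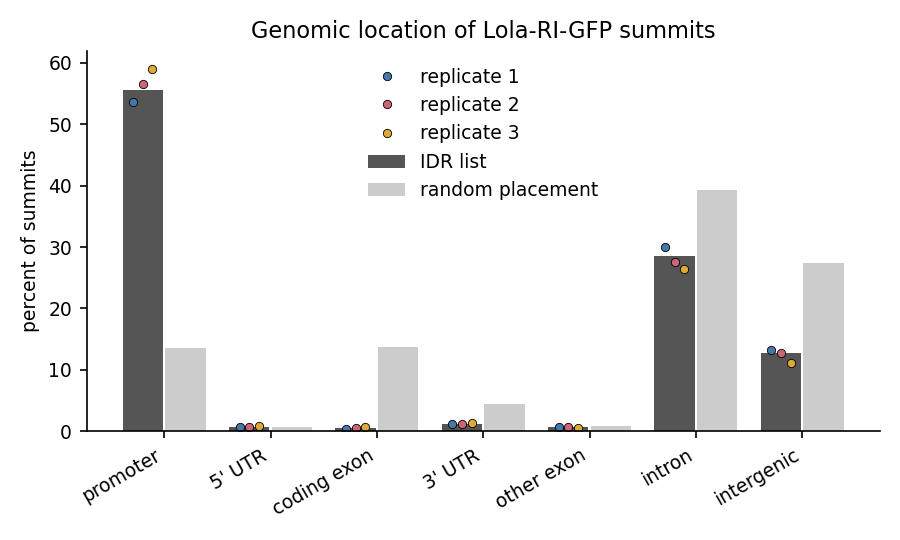
Percent of summits in each class of genomic location for the IDR list (dark bars), the 3 replicates (points) and random placement (light bars). Promoters held 55.5% of IDR summits against 13.6% at random, and coding exons 0.543% against 13.7%.

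The median distance of summits to the nearest TSS was 328 bp, against 3323.5 bp for random positions. Of summits within 500 bp of a TSS, 73.0% lay upstream, with a median position of -72 bp, and in the replicates 73.8%, 67.6% and 73.5% lay upstream. The promoter share was 63.2% in the fifth of peaks with the highest scores and 48.5% in the fifth with the lowest, while the intron share was 21.6% and 33.5%.

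**Figure D3:**
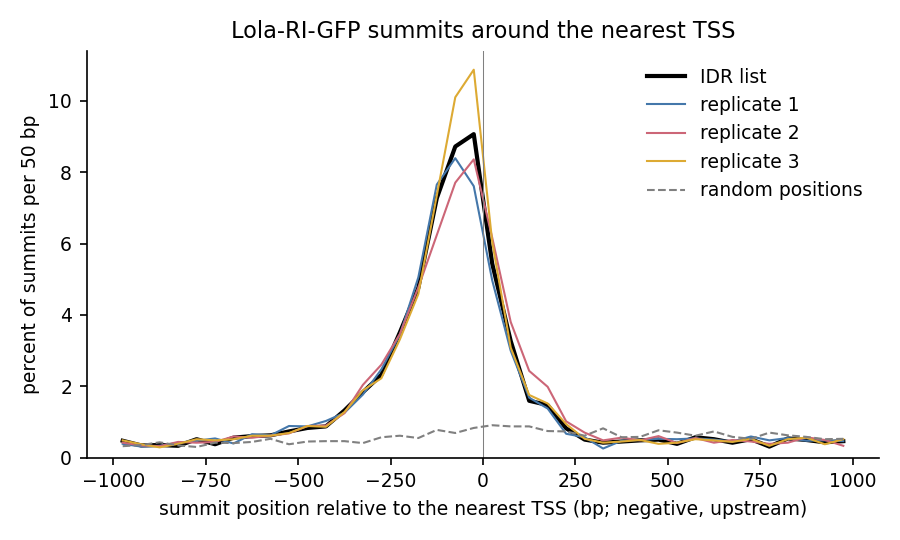
Distribution of summits around the nearest TSS in percent of all summits per 50 bp, for the IDR list, each replicate and random positions, with negative positions upstream. The IDR list and the replicates peak just upstream of the TSS, and 73.0% of the IDR summits within 500 bp lie upstream.

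Since the larvae were of mixed sex, with a lower X copy number in males, the X was compared with the autosome arms. Peak density was 70.98 per Mb on X, 69.1 on 2L, 71.1 on 2R, 71.9 on 3L and 64.0 on 3R. The X to autosome ratio was 1.03 (95% interval 0.978 to 1.09, exact binomial p = 0.251), with 0.972, 1.08 and 1.04 in the 3 replicates, so a difference was not detected. Without replicate 1 the ratio was 1.06 (exact binomial p = 0.0365). The small, largely heterochromatic chromosome 4 held 33 peaks, 24.5 per Mb (exact Poisson 95% interval 16.8 to 34.4), and 27.7 ± 4.22 per Mb in the replicates (SD, n = 3).

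At the promoter level, 4743 of 13945 protein-coding genes (34.0%, Wilson 95% interval 33.2 to 34.8) were bound, with 34.1% ± 1.90 in the replicates (SD, n = 3), and 3812 were bound in all 3. For some bound genes the summit lay nearer to the TSS of another gene. Among genes named below these included eIF4EHP, eIF6, Rpt3R, cos, Su(fu), sd, Cp190, nanos, Gr63a, Tm1, elav, loco, grh, ush, Fer1HCH and His2Av. In the noncoding lists they included tRNA:Gln-CTG-2-3, tRNA:Gln-CTG-3-1, snoRNA:CG43051-a and snoRNA:Psi28S-2622. Of the 34 gene lists, 11 passed the threshold, 4 with a higher and 7 with a lower bound share than all genes. Of these 11, 5 also passed it under each of the 9 alternatives run. They were cytosolic ribosomal proteins, cuticle proteins, midgut digestion, chemosensory receptors and histone genes. Of the 23 lists not past the threshold, 11 passed it in at least 1 alternative. With summits anywhere in the gene counted, axon guidance (59.0%, adjusted exact p = 0.0173), Hedgehog and Dpp (66.7%, p = 0.0245) and neurons (63.6%, p = 0.0296) were bound more often than all genes (37.2%). Counting the whole gene gives long genes more room for a summit. At promoters these lists were bound at 46.2%, 52.4% and 54.5%. Random lists matched on TSS number and gene length were bound there at 50.3%, 46.0% and 59.5% (adjusted permutation p = 0.833, 0.833 and 0.887).

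Genes of the ecdysone response, the steroid hormone cascade that drives moulting and metamorphosis, were bound more often than all genes, at 18 of 26 or 69.2% (adjusted Fisher exact p = 0.00136). The replicates gave 53.8%, 69.2% and 73.1%. Besides Eip75B and ftz-f1, the highest-scoring was ImpE1, with its peak on 3L from 8371682 to 8372853, rank 70. Further bound members, named after their values were seen, were the early genes br and Eip74EF, the receptor subunits EcR and usp, and the nuclear receptor genes Hr3 and Eip78C, while Eip93F, Hr4, Hr38 and Hr39 had no promoter summit. The call depended on the background. Random lists matched on TSS number and gene length, in 10 classes each, were bound at 54.1%, and against these the adjusted permutation p was 0.287. Without replicate 2 the adjusted exact p was 0.0621. Of 11 ecdysteroid synthesis genes, 2 were bound (18.2%, adjusted exact p = 0.461), both with low scores, mld at rank 6966 and shd at rank 7191.

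Cytosolic ribosomal protein genes had the most bound members among the lists past the threshold, at 66 of 93 or 70.97% (adjusted exact p = 6.83e-12), with an SD of 3.88 over the replicates. Matched random lists were bound at 30.8% (adjusted permutation p = 0.00136). The median rank of the bound members was 4152, against 3845 for all bound genes. The highest score belonged to RpL26 at rank 369, followed by RpL13A at 1303 and RpL34b at 1593, and the TSS nearest to each of these summits was that of a neighbouring gene. Translation initiation factors were bound at 43.2% of 44 (adjusted exact p = 0.279), led by eIF4G2 at rank 94, eIF4EHP at 360 and eIF6 at 1695. Proteasome genes were bound at 33.3% of 48 (Rpt3R at rank 2710, Rpn13 at 2935, Rpt1 at 3394) and oxidative phosphorylation genes at 33.7% of 86 (UQCR-Q at rank 648, ATPsynC at 1436, ND-ASHI at 1606), both with an adjusted exact p of 1.

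Of the signalling pathways, Notch and EGFR passed the threshold. Notch pathway genes were bound at 16 of 27 or 59.3% (adjusted exact p = 0.0261), led by the Notch inhibitor numb at rank 791, the receptor gene N at 897 and E(spl)m7-HLH, a target gene of the pathway, at 1210. The result did not hold against matched lists (38.7%, adjusted permutation p = 0.111), with promoters of 250 bp (adjusted exact p = 0.131) or without replicate 2 (adjusted exact p = 0.0639). EGFR pathway genes were bound at 13 of 20 or 65% (adjusted exact p = 0.0261), led by the kinase gene Raf at rank 208, the ligand gene spi at 1620 and the inhibitor gene aos at 1874. That result was lost in 7 of 9 alternatives, among them leaving out any 1 replicate (adjusted exact p from 0.112 to 0.249) and matched lists (adjusted permutation p = 0.287). In each replicate the EGFR share was 55%. Not past the threshold were the Hippo pathway (9 of 15, adjusted exact p = 0.104, led by sd at rank 200, CycE at 1726 and Mer at 3592), JAK-STAT (6 of 11, p = 0.279, with et, Socs36E and ken), Hedgehog and Dpp (11 of 21, p = 0.168, with cos, Su(fu) and Med), and Wnt (9 of 24, p = 0.940, with pan, sgg and nkd). Circadian clock genes were bound at 7 of 10 (adjusted exact p = 0.0801), with cyc at rank 263 followed by Pdp1 and vri. The clock list stood at 50%, 50% and 70% in replicates 1, 2 and 3. Cell death genes were bound at 5 of 11 (adjusted exact p = 0.639), with hid, Dark and Dcp-1. Heat shock protein genes were bound at 13 of 22 (59.1%, adjusted exact p = 0.0567). Their highest-scoring peak, at rank 332, lay at the adjacent promoters of Hsp22, Hsp67Bc and CG4456, on 3L from 9371779 to 9374127, and its summit counted for each of these genes. That list passed the threshold in 7 of the 9 alternatives and the Hippo list in 5, among them binding in all 3 replicates. Against matched lists, bound at 36.9% for heat shock and 46.3% for Hippo, neither passed (adjusted permutation p = 0.136 and 0.565).

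BTB domain transcription factors, the protein family of Lola, were bound at 10 of 16 or 62.5% (adjusted exact p = 0.0738), led by chinmo at rank 661, ttk at 741 and Cp190 at 800. Matched lists were bound at 60.9% (adjusted permutation p = 1). The BTB list passed the threshold with promoters of 1000 bp (68.8%, adjusted exact p = 0.0493) and with summits anywhere in the gene (87.5%, adjusted exact p = 0.000237). Genes of imaginal patterning factors were bound at 5 of 31 or 16.1% (adjusted exact p = 0.0801), namely sd at rank 200, nub at 3418, Dll at 3996 and, named after their values were seen, tsh and dan. Of 8 Hox genes, 0 had a promoter summit (adjusted exact p = 0.106), in the IDR list and in each replicate. Against matched lists, which were bound at 47.9% and 55.8%, the adjusted permutation p was 0.00136 for imaginal patterning factors and 0.0051 for Hox genes. With summits anywhere in the gene counted, 35.5% of imaginal patterning genes were bound against 37.2% of all genes (adjusted exact p = 1), and 50% of Hox genes, which turned the direction of that difference (adjusted exact p = 0.583).

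Among lists of differentiated tissues, those past the threshold were bound less often than all genes. Cuticle protein genes were bound at 9 of 115 or 7.83% (adjusted exact p = 3.97e-10). The highest-scoring peak lay between Lcp2 and Lcp3, larval cuticle genes, on 2R from 8434550 to 8435771, and ranked 26 in the IDR list and 12, 86 and 24 in the replicates. Cpr62Ba followed at rank 554, and the median rank of the 9 bound members was 2421, against 3845 for all bound genes. Midgut digestion genes were bound at 1 of 31 (3.23%, adjusted exact p = 0.000404), Jon74E at rank 2095. In replicates 1, 2 and 3 the midgut share was 3.23%, 6.45% and 12.9%. Of 179 chemosensory receptor genes, 3 were bound (1.68%, adjusted exact p = 1.89e-26), Or63a, Or49b and Gr63a. Of 15 antimicrobial peptide genes, 0 were bound (adjusted exact p = 0.0175), which matched lists (adjusted permutation p = 0.424) and another 3 alternatives did not hold. Germline genes were bound at 2 of 22 (9.09%, adjusted exact p = 0.0374), bgcn and nanos. This call was ended by 7 of 9 alternatives, among them leaving out any 1 replicate and promoters of 1000 bp, where the share was 31.8%. Replicates 1, 2 and 3 gave germline shares of 13.6%, 9.09% and 22.7%. Salivary gland glue and 71E genes were bound at 2 of 21 (9.52%, adjusted exact p = 0.0541), Sgs5 and Sgs1, at ranks 5601 and 5797. Without replicate 1 the share was 4.76% (adjusted exact p = 0.0237), and without replicate 3 also 4.76% (adjusted exact p = 0.0493). Random lists matched to the salivary gland list on TSS number and gene length were bound at 15.2% (adjusted permutation p = 0.833).

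Fat body genes were bound at 5 of 16 or 31.2% (adjusted exact p = 1), with high-scoring peaks at the lipid synthesis genes Desat1 (rank 80), FASN1 (240) and Lpin (284). Muscle genes were bound at 4 of 25 or 16% (adjusted exact p = 0.106), with the muscle transcription factor gene Mef2 at rank 389, sls at 6359 and Tm1 at 6680. Against matched lists, bound at 53.9%, the adjusted permutation p for muscle was 0.00227. Neuronal genes were bound at 12 of 22 (54.5%, adjusted exact p = 0.116), with elav at rank 846, cac at 1154 and Syx1A at 1378. Glial genes were bound at 6 of 11 (adjusted exact p = 0.279), with loco, moody and Gli. Axon guidance genes, a process in which lola is known to act, were bound at 18 of 39 or 46.2% (adjusted exact p = 0.197), with the kinase gene wnd at rank 46, Ptp99A at 377 and sli at 1218. Neural progenitor genes were bound at 6 of 19 (31.6%, adjusted exact p = 1), with the RNA-binding protein gene Syp at rank 109, grh at 472 and chinmo at 661. Haemocyte genes were bound at 3 of 14 (21.4%, adjusted exact p = 0.512), ush, Fer1HCH and crq.

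**Figure D4:**
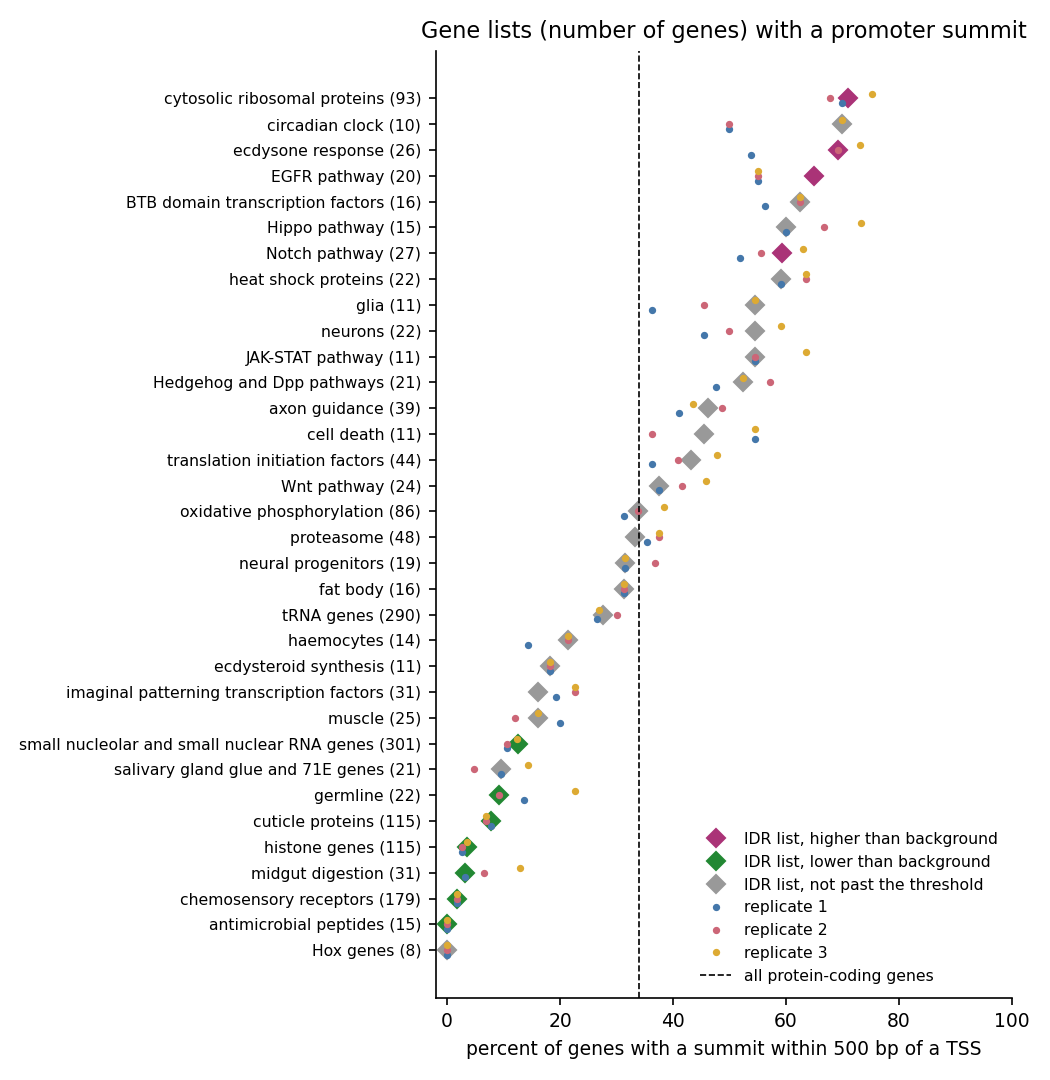
Percent of genes in each of the 34 lists with a summit within 500 bp of a TSS, in the IDR list (diamonds, coloured where the adjusted p passed 0.05) and in each replicate (points), with the 34.0% of all protein-coding genes as a dashed line. Cytosolic ribosomal proteins stand at 70.97% and chemosensory receptors at 1.68%.

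Histone genes were bound at 4 of 115 or 3.48% (adjusted exact p = 1.75e-14). Of these genes 111 lay in the repeated array on 2L, in a stretch from 21400402 to 21570290 without any peak of the pooled list. How reads from repeated copies were placed is not given in the sources used here. The other 4, His2Av, His3.3A, His3.3B and, named after its value was seen, His4r, were all bound. Without replicate 3, 1.74% of the list was bound. Transfer RNA genes were bound at 80 of 290 or 27.6% (adjusted exact p = 0.706), with a pair of peaks at ranks 137 and 143 in a group of glutamine tRNA genes (tRNA:Gln-CTG-2-3, tRNA:Gln-CTG-2-4 and tRNA:Gln-CTG-3-1) on 2L. Matched random lists were bound at 11.3%, below the tRNA genes (adjusted permutation p = 0.00136). Clustered tRNA genes can share a summit, as tRNA:Gln-CTG-2-4 and tRNA:Gln-CTG-3-1 did at rank 143, so this p may be too small. Small nucleolar and small nuclear RNA genes were bound at 38 of 301 or 12.6% (adjusted exact p = 8.32e-11). Matched lists were bound at 11.4%, and against these the difference was lost (adjusted permutation p = 0.653). With promoters of 1000 bp the list was at 25.9% against 33.7% (adjusted exact p = 0.0161). Their highest-scoring members were snoRNA:CG43051-a, snoRNA:Psi28S-2622 and snoRNA:Or-CD4.

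The gene of the factor itself, lola (FBgn0283521, 2R from 10481894 to 10543291, minus strand), had no IDR summit within the gene or 5 kb of it. Random windows of the same 71.4 kb held a mean of 4.90, and the one-sided permutation p for more summits was 1. In 23.3% of random windows there was also no IDR summit. No replicate had a summit there among its 9202 highest-scoring peaks. In the full lists, replicate 1 had 1 peak, from 10523664 to 10524107 at rank 24473 of 30000, and replicates 2 and 3 had 0.

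The last comparison asked which sequences lay at summits. Of 19 motifs fixed beforehand, 11 passed the threshold, and 7 of these passed it in all 6 alternatives run. Among the 7 were several core promoter elements. Motif 1 was found in 1.15% of summit windows against 0.136% of flanking windows (8.48-fold, adjusted exact p = 7.87e-28), the DNA replication-related element (DRE) in 1.52% against 0.315% (4.83-fold, p = 5.43e-26) and the TATA box in 16.9% against 12.3% (1.38-fold, p = 1.14e-24). Against positions matched on distance to the nearest TSS the ratio was 2.64 for Motif 1, 1.91 for DRE and 1.19 for the TATA box. It was 1.44 for GAGA, 2.74 for the GAGA repeat, 5.06 for the CTCF core and 1.55 for the Mef2 site. The GAGA motif occurred in 16.5% against 13.2% (1.25-fold, adjusted exact p = 7.69e-13) and the longer GAGA repeat in 1.67% against 1.10% (p = 0.000245). The CTCF core was found in 0.717% against 0.196% (3.67-fold, adjusted exact p = 3.57e-10; 2.35-fold without replicate 3) and the Mef2 site in 5.07% against 3.33% (1.52-fold, p = 1.90e-11). Summit windows had less GC than flanks (38.6% against 42.6%). Among the 6-mers with the lowest p, those made of A and T alone rose from 1.37-fold (AAAATA) to 1.75-fold (TTTAAA). Base composition was therefore not separated from the TATA box and Mef2 ratios. The Initiator (1.14-fold, adjusted exact p = 0.0026) and GATA (1.31-fold, p = 0.015) were higher than in flanks. Against positions matched on distance to the TSS the Initiator turned direction (0.939-fold, adjusted exact p = 0.214). Neither motif passed against such positions or in the stronger 4601 peaks, nor the Initiator without replicate 2 or GATA without replicate 1. The Zelda site (0.632-fold, adjusted exact p = 0.0224) and the Su(H) site (0.863-fold, p = 0.0159) were lower. Zelda did not pass without any 1 of the replicates, nor Su(H) without replicate 1 or in the stronger 4601 peaks. The single repeat of the nuclear receptor site was found in 0.0543% against 0.0978% of windows (adjusted exact p = 0.328).

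Ranked by exact p, the first of all 6-mers was AAAGCT. It was present in 23.3% of summit windows (95% interval 22.5 to 24.2) and 5.61% of flanking windows, a ratio of 4.16 (3.88 to 4.46). The replicates gave 22.8%, 20.1% and 25.5% (mean 22.8% ± 2.72 SD). Against positions matched on distance to the TSS, where 5.72% held it, the unadjusted exact p was 1.18e-266. The overlapping words AAGCTC (14.6% against 3.36%, a ratio of 4.34) and AAGCTT (11.5% against 2.47%, a ratio of 4.65) were also high. Their ratios to flanks exceeded that of AAAGCT, in fewer windows. In the fifth of peaks with the highest scores, 49.4% of summit windows held AAAGCT, and with falling score the other 4 groups of that size gave 24.7%, 16.7%, 14.1% and 11.7%, while flanking windows stayed between 5.05% and 6.22%. The word was present at 23.5% of summits outside promoters and 23.2% of those within. Of the 2080 6-mers, 447 were higher and 817 lower at summits after adjustment, and summit windows had a lower GC content than flanks (38.6% against 42.6%).

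**Figure D5:**
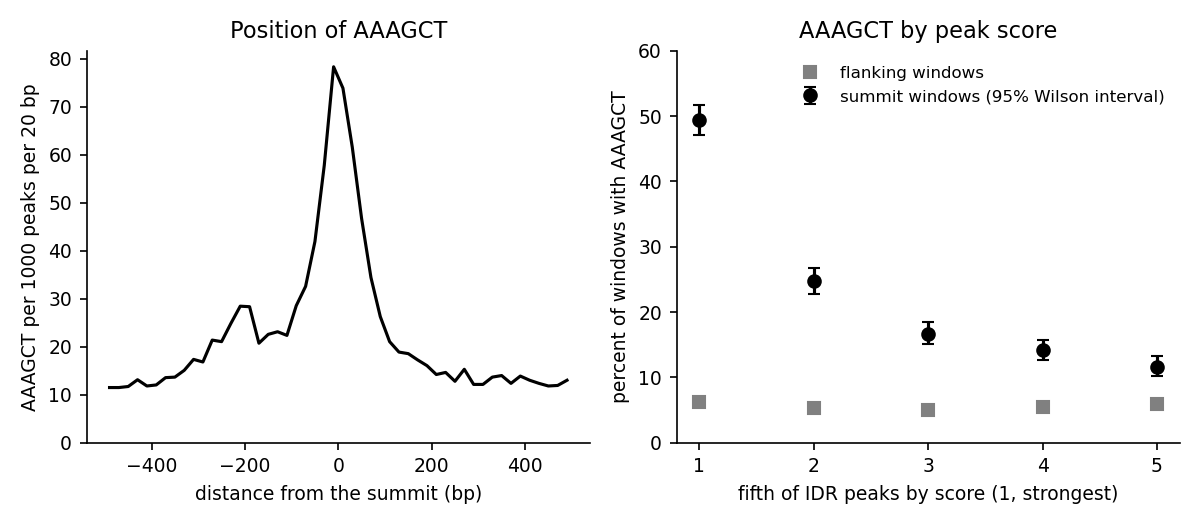
Left, occurrences of AAAGCT per 1000 IDR peaks and 20 bp around the summit. Right, percent of summit windows (with Wilson 95% intervals) and of flanking windows with AAAGCT for the IDR peaks in 5 groups by score, where 1 has the highest scores and holds the word in 49.4% of summit windows.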

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

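The added tests, chosen after the results were seen, were 1 summit per merged region for location and for peak density, random placement on unmasked bases and the correlation in the stronger IDR peaks. All others were planned. Agreement of lists, promoter share and the direction of all 5 location classes past the threshold kept their call in every alternative run, with the promoter share between 45.9% (250 bp) and 67.7% (1000 strongest peaks). The pooled list at the length of the IDR list is the same set, so that alternative tested nothing. The unknown depth limits what the weaker peaks show, and the lists of few genes give wide uncertainty. Of all alternative values of secondary results, those named elsewhere included and the void alternative left out, 386 kept their direction and side of the threshold, 30 newly passed it, 33 lost it and 45 reversed, and the cause of a change was not tested except where stated.

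Support of IDR peaks was 76.7% with at least 50% reciprocal overlap, 83.4% with summits within 100 bp and 99.3% for the stronger 4601 peaks, and 84.0%, 95.04% and 99.5% in the full lists. Leaving out 1 replicate gave 88.2% to 89.99%, and 98.3% to 99.0% in the full lists. The X to autosome ratio ranged from 1.00 to 1.06 without 1 replicate. The Spearman coefficient was 0.825 without replicate 3.

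These directions reversed, and none passed the threshold in the new direction unless a p is given. The 5′ UTR share was 1.5% with promoters of 250 bp, 2.06% from 1000 bp upstream to 100 bp downstream (adjusted permutation p = 0.000233) and 0.804% in the stronger peaks. The promoter width itself moves UTR summits between classes. Other exons held 1.10% of the 1000 strongest and 1.61% with protein-coding TSSs. At 250 bp, Wnt was bound at 25%, proteasome 31.2%, oxidative phosphorylation 32.6%, fat body 31.2% and neural progenitors 31.6%. At 1000 bp, oxidative phosphorylation was at 38.4% and tRNA genes at 37.6%, and counting the whole gene Hox was at 50%. In the stronger peaks, Hedgehog and Dpp were at 9.52%, cell death 18.2%, translation initiation 18.2%, fat body 31.2% and neural progenitors 21.1%. Against matched lists, axon guidance (46.2%), Wnt (37.5%), proteasome (33.3%), oxidative phosphorylation (33.7%), neurons (54.5%), tRNA (27.6%, adjusted permutation p = 0.00136) and small nucleolar and nuclear RNA genes (12.6%) turned, since matching moves the background and not the share. Bound in all 3 replicates, fat body was at 31.2%. With 1 replicate left out and binding required in each remaining list, oxidative phosphorylation ranged from 25.6% to 30.2%, against 31.4% to 38.4% in single replicates. Under that rule fat body stayed at 31.2%, Wnt ranged from 29.2% to 37.5%, proteasome from 29.2% to 31.2% and neural progenitors from 26.3% to 31.6%. In windows of 100 bp to either side, the ratio was 1.02 for the CACA repeat and 0.952 for TCF. Against distance-matched positions it was 1.5 for the CACA repeat (adjusted exact p = 5.03e-05, while against flanks it was 0.699 in the stronger peaks, p = 0.00239, and 0.829 without replicate 3, p = 0.0257), 1.09 for the E-box, 0.939 for the Initiator, 1.12 for AP-1 and 0.997 for TCF. Without 1 replicate AP-1 ranged from 0.957 to 1.10 and TCF from 0.333 to 0.8.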

Other observations

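All gene counts, families and tests in this part were chosen after the results were seen. Several genes held many summits along their length rather than at 1 promoter. Eip75B held the highest number of all protein-coding genes, 36 IDR summits over 113.7 kb, and 34, 42 and 37 in replicates 1, 2 and 3. Next by number were another early ecdysone gene, Eip74EF, with 25 over 60.7 kb (21, 24 and 25), kirre, an adhesion gene of myoblast fusion, with 22 over 394.1 kb, CG1677 with 21 over 124.7 kb, and the ecdysone receptor gene EcR with 19 over 81.2 kb (19, 17 and 16). The genes sbb, shn and tara also held 19 each, and CG46385 and Svil 18 each. Per 10 kb of gene the order among these 10 differed, with 5.48 summits in tara, 4.12 in Eip74EF, 3.95 in CG46385, 3.26 in shn, 3.17 in Eip75B, 2.34 in EcR and 0.558 in kirre. Without the lower-scoring summits of close pairs described below, Eip75B held 34, kirre 22, CG1677 19, Eip74EF 18 and EcR, sbb and tara 17 each. Among 51 families of protein-coding genes with a shared symbol and at least 10 members, mRpL (mitochondrial ribosomal proteins of the large subunit) was the family with a higher bound share that passed the threshold, with 26 of 47 or 55.3% (adjusted Fisher exact p = 0.0257), led by mRpL41 at rank 307, mRpL33 at 414 and mRpL20 at 540. The summits of mRpL33 and mRpL20 lay nearer to the TSSs of norpA and Icmt. The small subunit family, mRpS, did not pass, with 12 of 26 (46.2%, adjusted exact p = 0.422). The Rab family of small GTPases missed it with 18 of 31 (58.1%, adjusted exact p = 0.0511).

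Another 5 families were bound less often than all genes. Odorant-binding proteins (Obp) were bound at 2 of 51 (adjusted exact p = 1.64e-05), Obp99b and Obp83g. Seminal fluid proteins (Sfp) were bound at 1 of 28 (adjusted exact p = 0.00491) and accessory gland proteins (Acp) at 0 of 19 (p = 0.00688), both classes known from the adult male. The Osiris family (Osi) was bound at 1 of 25 (adjusted exact p = 0.00688) and the pickpocket channels (ppk) at 2 of 28 (p = 0.0207). Of the latter, ppk12 had a strong summit at rank 281, which lay nearest to the TSS of CG10344.

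Of 1091 pairs of neighbouring IDR summits up to 250 bp apart, none closer than 199 bp, the summit at the higher coordinate had the lower score in 1076 (98.6%), and the replicates gave 99.2%, 99.5% and 98.8%. For pairs over 250 and up to 500 bp apart it was 75% of 104 in the IDR list and 62.0%, 62.0% and 66.4% in the replicates. The direction in which coordinates run along a chromosome is arbitrary. An order this regular, in the IDR list and all 3 replicates, therefore argues for a technical origin rather than a property of binding. Which step of the processing gave it was not tested, because reads were not used here. The lower-scoring summits at the higher coordinate of close pairs made up 11.7% of the IDR list. AAAGCT was present at 11.4% of them and at 24.9% of all other IDR summits. Without them the word was present in 24.9% of summit windows against 5.48% of flanks, in 52.2% of the fifth with the highest scores, and in 11.9% of the fifth with the lowest. Around all IDR summits AAAGCT was uneven, with 28.5 occurrences per 1000 peaks from -220 to -200 bp and 14.2 from 200 to 220 bp. Whether the close pairs gave this unevenness was not tested.

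AAAGCT at summits, more often at stronger peaks, was weighed against 3 technical explanations. Base composition of the summit windows would raise other words of the same letters equally, but the highest ratio among the 119 others was 1.82 and their median 1.07, against 4.16. A sequence common to promoters was argued against by a ratio of 4.04 (95% interval 3.64 to 4.48) at summits outside promoters. Less precise summits of weaker peaks would even out in windows of 250 bp to either side, yet there 75.2% (73.1 to 77.1) of the fifth with the highest scores and 36.7% (34.5 to 38.9) of that with the lowest held the word. The word may therefore be part of the sequence Lola-RI recognises, a hypothesis found and examined on the same peaks, and recognition by a partner protein stays open because a single group allowed no test of it.

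The absence of summits at lola was weighed against 2 explanations. A chance gap for a window with that many TSSs was argued against, since 1.22% of 10000 random windows of 71.4 kb with at least 15 TSSs held no summit of the pooled list, although of all random windows 17.0% held none. Removal of the window from the lists stays open, with 1 of the 3 replicate lists holding a summit there, of low rank. The stretch without pooled summits ran on 2R from 10444955 to 10564244 (119 kb), and the arms held 65 stretches at least as long. Extra genomic copies of this region in the tagged line could also lower its enrichment over control, which was not tested here because neither reads nor the control were used.

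Ribosomal protein promoters were bound often, with a median rank of 4152 against 3845 for all bound protein-coding genes and 1 of 66 (1.52%) against 13.9% in the 10% of IDR peaks with the highest scores. Summits of neighbouring genes were argued against as the whole cause, since among genes with no other TSS within 1000 bp, 11 of 21 ribosomal protein genes (52.4%) and 23.8% of others were bound (Fisher exact p = 0.00759). AAAGCT was present at the promoter summit of 3 of the 66 bound ribosomal protein genes (4.55%). Random draws within 5 score groups from all bound protein-coding genes, the ribosomal ones included, gave 18.0% (one-sided permutation p = 0.0015). Genes that share a summit were each counted. No biological explanation was tested, since there was a single group.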
